A study of Mus musculus with 2 samples.

How the data were processed

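The material was telencephalon of mouse embryos at embryonic day 14.5, per the labels. Chromatin from this tissue was immunoprecipitated with an antibody against Arx, a paired-type homeodomain transcription factor of migrating and maturing forebrain interneurons, and a library without antibody (input) was prepared beside it. Per the labels' protocols, tissue was fixed in 4% paraformaldehyde for 3 h in the cold, the sample was boiled in citrate for 15 min, DNA was sheared by sonication, and libraries were made with a kit that works from small amounts of DNA. The labels give 1 ChIP library and 1 input library, so no value has a replicate check and no comparison between conditions can be tested.

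The authors deposited 1 list of peaks, called on the ChIP library with the input as control. The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.9, MACS3 3.0.0b1, MACS2 and deepTools 3.5.1, and the mouse build GRCm38 (mm10), without saying which tool made which file. Which of the 2 MACS programs called the peaks, and with which threshold, is not given in the sources used here. For each peak the authors' list holds a start, an end, a summit, a fold enrichment (a linear ratio of ChIP over background at the summit), a −log10 p-value, a −log10 q-value and a score. The deposited score equalled 10 times the −log10 q-value, taken to a whole number, in 100% of peaks. These values belong to each peak and were used to describe, rank or filter peaks within the list. All coordinates are on mm10, counted from 1.

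The library's read total is not given in the sources used here, so depth was read from the peaks. Assuming that the fold is (fragments + 1) / (background + 1) and that p is the upper Poisson tail, the number of ChIP fragments at each summit and the local background were solved from the authors' fold and −log10 p. The solution lay within 0.02 of a whole number of fragments in 100% of the 9739 peaks. Poisson 95% intervals are given for these fragment counts and cover counting error only; fragments are PCR products, not independent molecules.

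Peaks on chromosomes 1 to 19, X and Y were analysed, and those on other contigs were counted apart. Summits were set against a RefSeq gene table of GRCm38.p6 with the start, end and kind of each gene, 21887 of them protein-coding. The table holds no strand, exons or DNA sequence. Distances to transcription start sites, exon and intron classes, promoter GC content, repeats and every test of the TAATTA and paired TAAT sequences, all planned before the data were examined, were therefore not run. In place of the planned measures, others were chosen after the data were seen. These were whether a summit lay inside a protein-coding gene and whether it lay within 1 kb of either end of a gene. A further one was on which side of an isolated end of a protein-coding gene it lay. An end was isolated if its gene was 2000 bp or longer and no other annotated gene reached the 2000 bp outside it. Other genes on the inner side were allowed. Shares have Wilson 95% intervals. They were compared with 1000 random placements of the summits between the first and last annotated gene of the same chromosome. For shares of summits, both treat summits as independent, although several often share 1 gene. Those intervals and random ranges are therefore likely too narrow.

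For gene lists, each summit was given to the protein-coding gene whose span was nearest within 100 kb, the shortest where spans overlapped. The share of a list's genes with 1 or more summits was compared with 10000 random lists of the same size, matched on decile of the gene's territory (its length plus the flanking bases nearest to it within 100 kb). A percentile outside 2.5 to 97.5 counted as standing apart, and the share of random lists as extreme, doubled for both sides, was adjusted by Benjamini-Hochberg over the 22 lists fixed before the data were examined. A first form of this test counted only summits inside a gene's span and matched random lists on gene length. It was replaced after its results had been seen, since the nearest-gene form is closer to the planned one, and its values are among the alternatives. The replacement raised the percentile of the interneuron list from 97.7 to 99.6 and that of the cortical list from 94.4 to 99.97. These percentiles describe 1 library and are not p-values, since genes are not replicates. A further 9 lists (epidermis, hair follicle, mature skeletal muscle, developing muscle, heart muscle, dermal connective tissue, abundant transcripts of embryonic brain, intestine and housekeeping genes) were written after the strongest peaks had been seen and were adjusted among themselves. The same test was repeated with 4 other sets of summits: inside protein-coding genes, outside every gene, outside protein-coding genes, and outside protein-coding genes and pseudogenes. For the 3 outside sets, random lists were matched on decile of flank length. The last set was added after several summits outside protein-coding genes were seen to lie in pseudogenes. Median folds of classes of peaks were compared by two-sided permutation tests over peaks with 100000 resamples; peaks of 1 list are not replicates.

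Genes were named by a rule fixed before the data were examined: Arx, its partners in the interneuron lineage and its reported targets in any case; the genes of the 10 peaks of highest fold and the 5 of highest −log10 q; the 5 genes with most summits; and up to 4 genes with the summit of highest −log10 q from each list that stood apart and from the interneuron, reported-target and cortical lists. Other genes are named as members of a list, and were chosen after their values were seen.

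The list test was tested on simulated data with 21887 genes and 200 lists of 30 genes per setting. Lists with no added summits stood apart in 5.5% of draws, lists with a doubled rate (2-fold) were found above in 70.5% and lists with a 3-fold rate in 99.0%. Genes were hit independently there. These rates therefore do not cover lists of neighbouring genes, such as olfactory receptors and histones, or lists of other sizes. In a simulation of the share of summits inside protein-coding genes, the expected share was 70.3% and the share found was 70.5%. Alternatives varied the threshold on peaks, the distance, the overlap that counted, the assignment, the matching and the set of summits. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.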

Results

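The study asked where Arx lies on chromatin of the embryonic forebrain. One anti-Arx ChIP library of embryonic telencephalon was set against 1 input library, and the authors' list held 9739 peaks. Of these, 9689 lay on the 21 chromosomes and 50 on 6 other contigs. Peaks were narrow, with a median width of 133 bp (25th to 75th percentile 108 to 181 bp), and 93.3% were 300 bp or shorter. The median fold of ChIP over background was 7.42 and the highest was 47.21. The median summit held 19 ChIP fragments (Poisson 95% interval 11.4 to 29.7) over a local background of 1.61, so the weaker peaks rest on few fragments. With 1 library per group there was no replicate check for any value given here.

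Most summits lay inside genes. Of the 9689 summits, 8482 (87.5%, Wilson 95% interval 86.9 to 88.2) fell inside a protein-coding gene, against a median of 40.6% in random placements, a 2.16-fold excess. Sequence outside every annotated gene held 590 summits (6.09%, 5.63 to 6.58), against 51.3% in random placements. Within 1 kb of a gene end lay 2321 summits (24.0%, 23.1 to 24.8), against 6.47%. None of the 1000 placements was as extreme for any of these shares. Pseudogenes with no protein-coding gene over them held a further 450 summits (4.64%), with a median fold of 8.88. Protein-coding genes with a summit inside numbered 3936 (18.0% of 21887), and 390 of them held 5 or more summits.

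The change at the edge of genes was abrupt. There were 25213 ends of protein-coding genes with no other gene in the 2000 bp outside the end. At these, 307 summits lay in the first 500 bp inside the gene and 19 in the first 500 bp outside it, so that 94.2% were inside (91.1 to 96.2). Over 2000 bp the numbers were 1287 and 48. The outside was free of other genes by choice, so this imbalance largely restates the low share of summits outside every gene. What the profile adds is the place of the change. The first 100 bp inside the end held 18 summits, and each later stretch of 100 bp held 54 to 80.

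**Figure D1:**
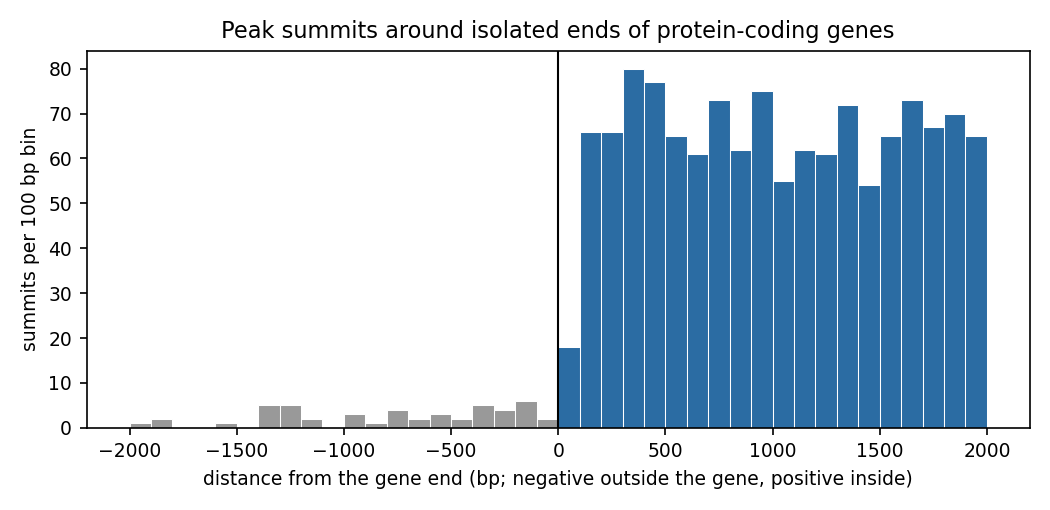
Number of peak summits per 100 bp bin (y axis) by distance in bp from 25213 isolated ends of protein-coding genes (x axis; both ends of genes pooled, positive values inside the gene). Within 500 bp of the end, 307 summits lie inside the gene (blue) and 19 outside (grey).

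The strongest peaks lay in genes of skin, muscle and connective tissue. By fold, the first was in Krt5, the type II keratin of basal epidermis (gene 110308; chromosome 15, 101708767 to 101709109), with a fold of 47.21 and 101 fragments (82.3 to 122.7). It was followed by Krt6b (44.4), Acta1, the actin of skeletal muscle (41.5), Col1a1, a chain of type I collagen (41.3), Krt15 (40.3), Myh1, a fast myosin of skeletal muscle (40.1), Krt14, the partner of Krt5 (39.8), Ahnak (39.8), the histone gene H2ac18 (38.8) and Krt16 (38.4). The 5 peaks of highest −log10 q were in Krt5, Krt6b, Krt16 and Col1a1, with Krt6b holding 2 of them. All of these summits lay inside the named gene. Genes given most summits were Ttn, the giant protein of the sarcomere, with 112, Lrp1 with 31, Myh1 with 29, Huwe1 with 28 and Macf1 with 23. Along the Krt6b, Krt6a and Krt5 genes there were 21 peaks of fold 5.599 to 47.21, all within the genes. Krt6a and Krt6b, like the histone genes, have close copies, so fragments could be shared between them by the alignment.

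**Figure D2:**
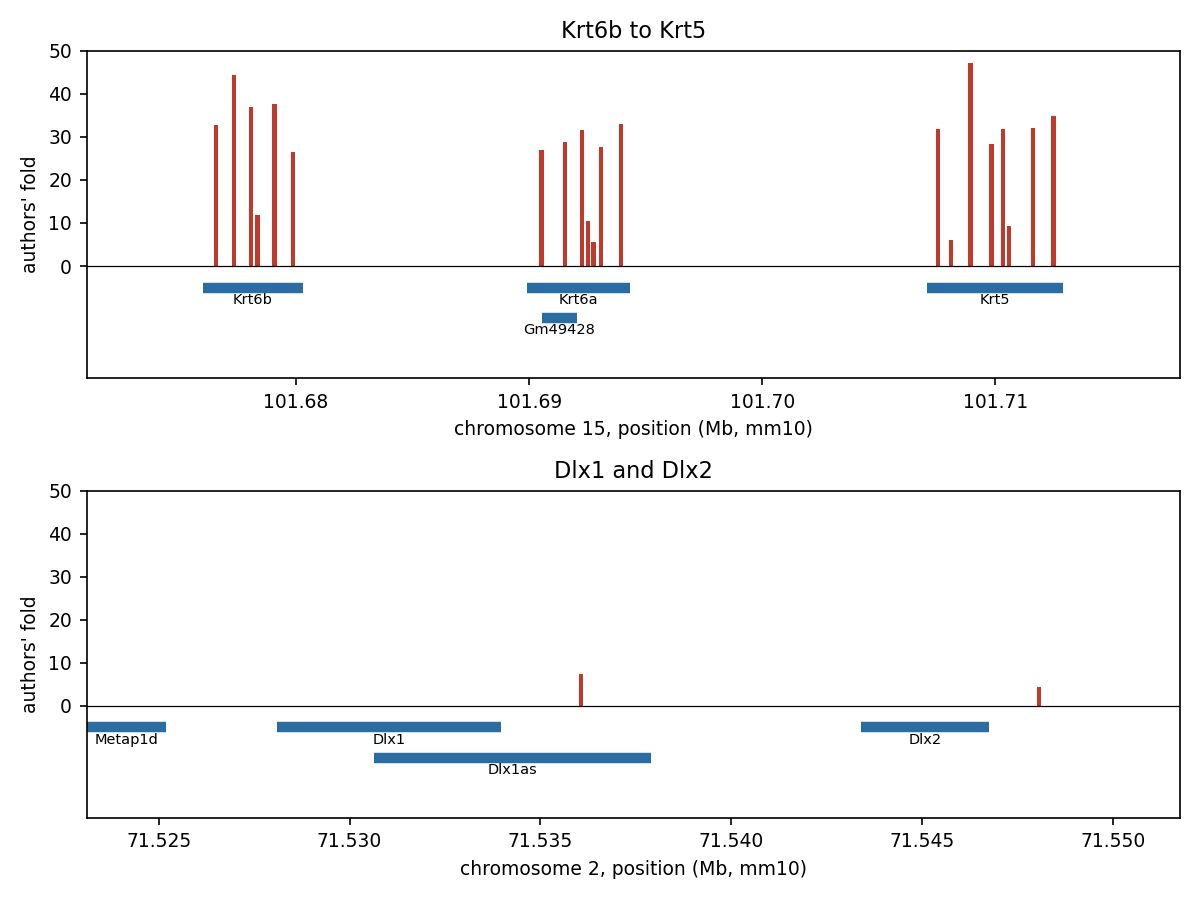
Peaks (red bars, height the authors' fold, placed at the peak's centre and wider than the peak) and annotated genes (blue) by position in Mb on mm10, for the Krt6b to Krt5 region of chromosome 15 (top) and the Dlx1 and Dlx2 region of chromosome 2 (bottom). The keratin region holds 21 peaks, reaching a fold of 47.21, and the Dlx region 2 peaks of fold 7.51 and 4.49, both outside Dlx1 and Dlx2.

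Which groups of genes lay near summits was asked with 22 lists fixed before the data were examined. Of these, 10 stood above the random range and 1 below, where about 1.1 would by chance if genes were hit independently. Many histone and olfactory receptor genes are neighbours and so are not independent. Within 100 kb, 9238 summits were given to 4308 protein-coding genes (19.7%). Genes that most cells use were often hit. Ribosomal protein genes held summits in 35 of 40 (87.5%, Wilson 73.9 to 94.5; random mean 15.6%), with folds of 21.3 in Rpl32, 24.2 in Rps18 and 20.2 in Rpl19; the summit given to Rps29 (29.3) lay 0.240 kb from it, in the signal recognition particle RNA gene Rn7s1. Chromatin regulators held summits in 23 of 30 (76.7%, 59.1 to 88.2; random 22.3%), among them Arid1a (23.5), Kdm6a (23.5), Crebbp (21.6) and Kmt2d (22 summits). Histone genes, a list taken by symbol that also holds replication-independent and testis variants, held summits in 61 of 87 (70.1%, 59.8 to 78.7; random 15.8%), led by H2ac18, H2ac6 (34.3), H2ac19 (32.2) and H4c2 (30.5). Olfactory receptor genes, silent in most tissues, were given summits in 8 of 1110 (0.721%, 0.366 to 1.42; random 15.1%), and none held 1 inside. These 4 lists had an adjusted share of 0.000880.

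Signalling and neurodevelopmental lists also stood above the range, as did the lists of genes that most cells use. Random lists were matched on territory and not on expression, so these calls do not separate expressed genes from genes near Arx. Wnt pathway genes held summits in 22 of 30 (73.3%, 55.6 to 85.8; random 24.9%; adjusted share 0.000880), with Ctnnb1, which encodes β-catenin, at a fold of 26.3, Apc at 17.3, Fzd1 at 16.0 and Lrp5 at 14.6. Radial glia and Notch genes held summits in 14 of 25 (56.0%; random 23.7%; adjusted 0.00377), led by Vim (29.8), Nfix (23.3), Notch2 (15.7) and Sox9 (12.5). Migration and axon guidance genes, with 17 of 34 (50%; random 29.8%), and Sonic hedgehog pathway genes, with 8 of 14 (57.1%; random 25.4%), were above the range but not after adjustment (0.0519 for both). In the first, Pafah1b1 reached 15.4, Nrp2 12.7 and Cxcl12 11.97, while the strongest summit given to Dab1 (34.0) lay 55.0 kb away in the pseudogene Gm12715; in the second, the folds were 17.5 in Ptch1, 11.02 in Gli2, 10.1 in Ptch2 and 9.96 in Smo. Endothelial and meningeal genes, with 9 of 20, stood just above (percentile 97.6, adjusted 0.144), through Col1a1, Col1a2 (36.0), Col3a1 (19.9) and Foxc1 (19.04), and fell within the range under several alternatives.

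The interneuron list, which holds regulators and products of the ganglionic eminences, had summits near 18 of 40 genes (45.0%, Wilson 30.7 to 60.2; random 25.8%; percentile 99.6; adjusted 0.0286). Its strongest members were Maf (32.1), Mafb (21.3) and Zeb2 (20.7), transcription factors that other tissues also use, with summits inside the gene, and Cxcr4 (23.9), whose summit lay 68.1 kb away in the pseudogene Gm6170. Taking only summits inside genes, 13 of 40 had 1, and the call turned on the matching: the percentile was 93.1, within the range, with lists matched on territory and 97.7, above it, with lists matched on gene length. Cortical excitatory genes had summits near 16 of 30 (53.3%, 36.1 to 69.8; random 26.0%; adjusted 0.00377) and, for summits inside genes, percentiles of 91.3 and 94.4 under these matchings, both within the range. Bcl11b (15.5) and Cux1 (12.7) held theirs inside, and those given to Pou3f2 (15.4) and Slc17a6 (11.6) lay in the pseudogenes Gm11878 and Gm7336. Both calls were lost under some stricter thresholds on peaks: the interneuron list had percentiles of 97.3 with −log10 q of at least 5 and 94.4 at or above the median fold, but 98.4 in the strongest 1000. The cortical list had 99.6 with −log10 q of at least 5, 97.47 at or above the median fold and 60.8 in the strongest 1000. The other 11 fixed lists were within the range: reported Arx targets (2 of 5), cell cycle (7 of 30), epilepsy and intellectual disability (11 of 32), neuronal synapse (5 of 30), glia (5 of 20), microglia and blood (5 of 20), liver and muscle (7 of 20), pancreatic islet (2 of 20), germline (2 of 20), Hox genes (6 of 29) and other homeobox genes (11 of 32). In the liver and muscle list (percentile 97.3) the 7 genes were Acta1, Myh1, Myh4, Des, Ckm, Tnnt3 and Mylpf, all of muscle.

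**Figure D3:**
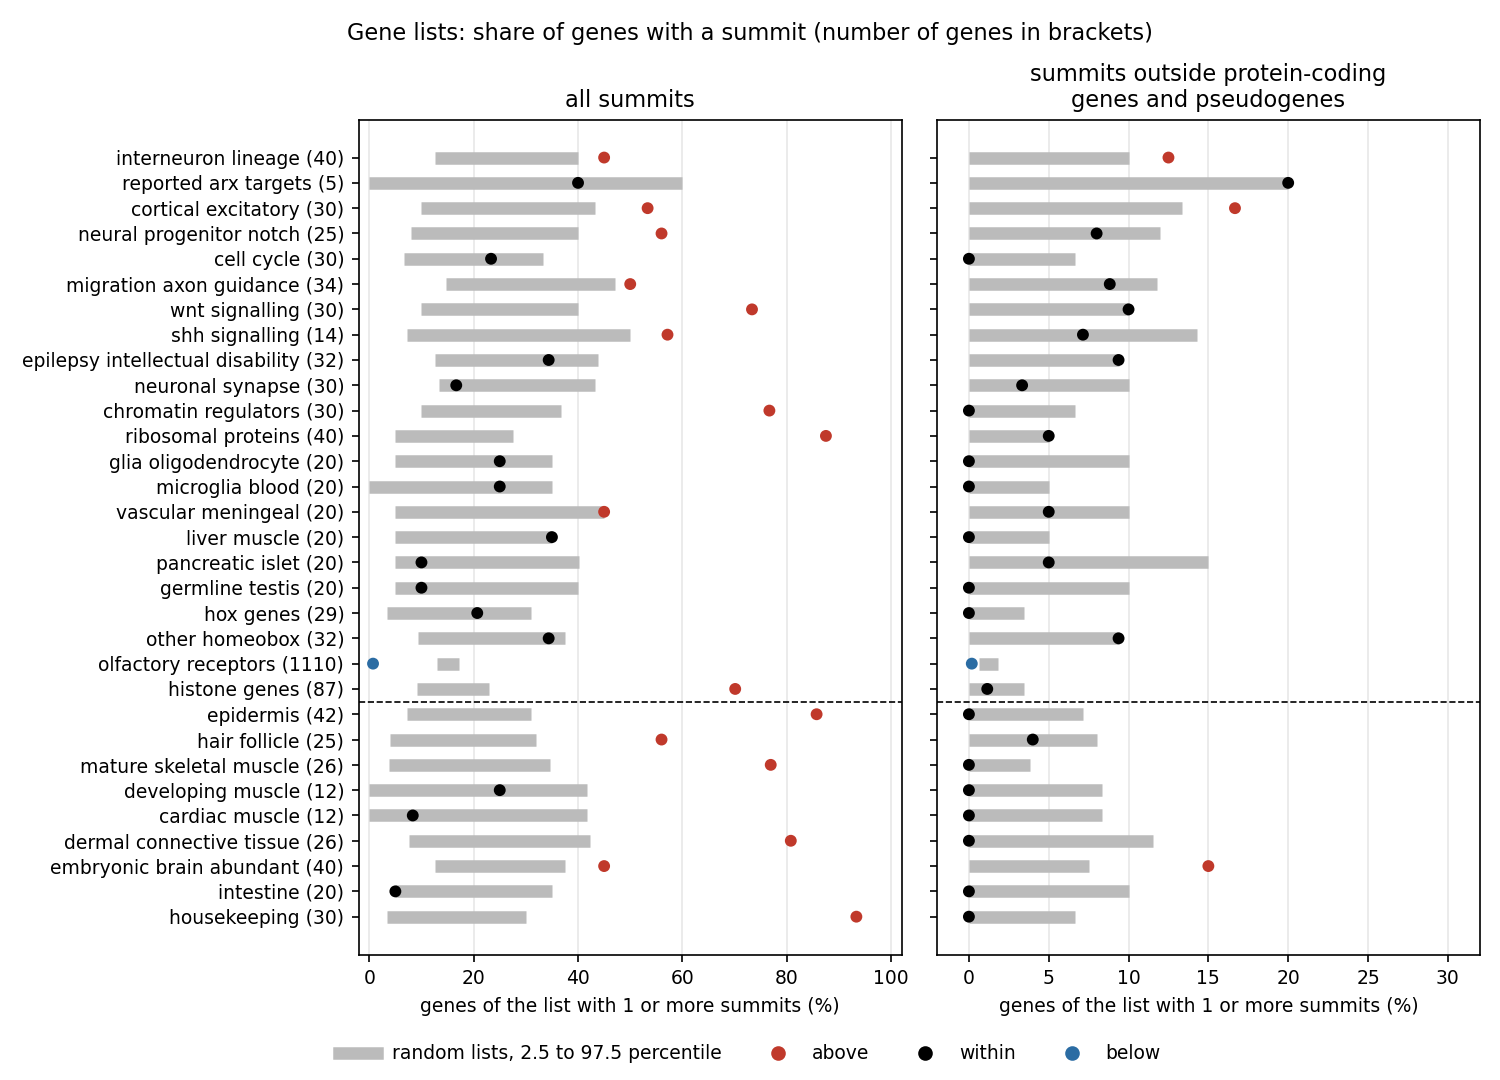
Percent of each list's genes with 1 or more summits (x axis) for all summits (left) and for summits outside protein-coding genes and pseudogenes (right; different x scale), with the number of genes in brackets. Grey bars span the random range over 10000 lists, point colour gives the side of that range, and lists under the dashed line were written after the strongest peaks were seen. Epidermis reaches 85.7% on the left and 0% on the right.

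Of the genes at the centre of the study, Arx and the interneuron genes named in every case (Dlx1, Dlx2, Dlx5, Dlx6, Lhx6, Nkx2-1, Gad1 and Gad2) held no summit inside. Arx itself (gene 11878; chromosome X, 93286507 to 93298357) had its nearest summit 111.1 kb away. No summit lay within 100 kb of Lhx6, Gad2, Ebf3, Shox2 or Cdkn1c, and none was nearest to Gad1 or Dlx5. Summits did lie beside other members of the group. On chromosome 2, 1 peak (71535988 to 71536156, fold 7.51, 18 fragments, 10.7 to 28.4) lay between Dlx1 and Dlx2 inside the antisense gene Dlx1as, and another (71547990 to 71548153, fold 4.49, 10 fragments, 4.80 to 18.4) lay 1264 bp beyond Dlx2. On chromosome 6, 3 peaks (first start 6870034, last end 6872209) of fold 5.57, 3.98 and 5.23 lay between Dlx6 and Dlx5, and on chromosome 12, 2 peaks lay 60.7 and 73.0 kb from Nkx2-1 with folds of 9.51 and 6.11. Lmo1, a reported Arx target, had 4 summits around it and none inside, of which the nearest was 188 bp from a gene end (109175358 to 109175517, fold 4.64) and the strongest was at 109191259 to 109191835 on chromosome 7 (fold 8.03, 34 fragments, 23.5 to 47.5). Kdm5c, another reported target, held 11 summits inside it, reaching a fold of 18.9 (39 fragments, 27.7 to 53.3). It also stands in the chromatin regulator list, where 23 of 30 genes held a summit inside, so its summits are not particular to an Arx target.

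Summits outside protein-coding genes and pseudogenes, a set chosen after the data were seen, numbered 757 (7.81%) and had a median fold of 4.80. Near them, 5 of 30 cortical excitatory genes (Pou3f3, Satb2, Foxg1, Mef2c and Bhlhe22) and 5 of 40 interneuron genes (Nkx2-1, Pbx3, Dlx1, Dlx2 and Dlx6) stood above the random range, with percentiles of 99.7 and 98.9, but neither after adjustment over the 22 lists (0.119 and 0.280). Olfactory receptors (2 of 1110) were below it, with an adjusted share of 0.00440. The other 19 fixed lists were within the range. With summits in pseudogenes kept in, the cortical list had 7 of 30 genes and an adjusted share of 0.0308, and the interneuron list 6 of 40 and 0.363. In that set the list of other homeobox genes was also above the range, with 5 of 32 (percentile 98.6, adjusted 0.340). Outside every annotated gene, no fixed list was above the range: the cortical list had 2 of 30 genes (percentile 84.6) and the interneuron list 3 of 40 (92.2). The summits given to Pou3f3, Foxg1, Mef2c, Pbx3 and Dlx1 lay inside other annotated genes, such as Dlx1as. The sets in this paragraph are 3 of the 4 further sets of summits that were tested.

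The median fold was 7.57 for summits inside protein-coding genes and 5.599 for the others (two-sided permutation test over peaks, p = 1e-05, the smallest that 100000 resamples can give). The others were mixed, with a median fold of 8.88 for the 450 in pseudogenes and 4.80 for the remaining 757. Within 1 kb of a gene end the median fold was 7.84, against 7.24 farther away (permutation test, p = 1e-05, again the smallest). Among the 1000 peaks of highest −log10 p, the first difference had the opposite sign. The X chromosome, which carries Arx, held 348 summits (3.59%, Wilson 3.24 to 3.98), while it makes up 6.31% of the annotated span and 4.41% of protein-coding genes. Chromosome 11, which carries the type I keratin and fast myosin clusters, held most summits (996, 10.3%, 9.69 to 10.9) with 4.51% of the span and 7.35% of protein-coding genes. Per 100 protein-coding genes, chromosome 15 had 63.7 summits and chromosome 11 had 61.9.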

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

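No test in this part was chosen after its result was seen. Peaks on contigs outside the chromosomes entered no comparison, and their number was set beside the 3 that a count of 0 allows. The contig JH584304 held 41 peaks and the contig GL456370 held 4. The peaks on JH584304 had a median fold of 1.67, against 7.42 on the chromosomes. An explanation set before it was tested is that this contig holds sequence present in many copies, to which reads of both libraries pile up: the median local background at its peaks was 78.9 fragments, 49.0 times that of the chromosomes, and the lowest was 51.2. This background was solved from the fold and the p-value, and a peak of so low a fold passes the caller's threshold only over a high background. The outcome was therefore largely fixed by the low fold, and it does not decide for many-copy sequence. No biological explanation was tested. The 4 peaks on GL456370 had a median fold of 8.15 over a background of 2.10.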

How the results depend on the processing

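Thresholds on peaks, distances, overlaps, merging, covered bases and −log10 q in place of fold were planned; every other assignment, matching and set of summits, genes or lists was chosen after seeing the data. The shares inside genes, near gene ends, at isolated gene ends and outside genes kept their side of the random range (or of 50%) under each alternative run; at isolated ends, 98.5% of summits lay inside with −log10 q of at least 5. The number of peaks fell to 4851 at or above the median fold and was 1000 by construction in the strongest set; the X share was 4.00% at or above the median fold. The fold difference between summits inside and outside protein-coding genes turned to −0.0600 at or above the median fold (permutation test, p = 0.70) and −1.80 in the strongest 1000 (permutation test, p = 0.014); the cause was not tested.

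The interneuron list left the upper range (percentiles) with −log10 q of at least 5 (97.3), at or above the median fold (94.4), inside genes (93.1, but 97.7, still above, matched on length), within 5 kb of a gene end (95.6) and outside every gene (92.2). The cortical list did so at or above the median fold (97.47, just under the limit), in the strongest 1000 (60.8), inside genes (91.3; 94.4 matched on length), within 5 kb of an end (97.4) and outside every gene (84.6). In the strongest 1000, the migration list had 1 of 34 genes (54.8). Histone genes, too short to have them, turned to 1.55 with summits over 1 kb from a gene end.

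Of 22 fixed lists, 10 stood above the range; other thresholds, assignments and matchings gave 7 to 12, summits outside every gene 0, outside protein-coding genes 3, and outside these and pseudogenes 2. In these 3 sets, in that order, some lists above the range with all summits fell below the random mean. Percentiles were 33.5, 21.96 and 29.7 for chromatin regulators and 29.9, 52.1 and 25.9 for epidermis. They were 41.4, 34.2 and 39.2 for mature muscle, 37.5, 27.2 and 35.1 for housekeeping and, in the first and last, 26.6 and 21.8 for dermal genes. Others stayed above the mean but within the range, among them ribosomal proteins (85.5, 92.1 and 97.0), Wnt genes (90.9, 97.1 and 96.5), radial glia and Notch genes (72.0, 78.0 and 89.7) and histones (67.6, 89.8 and 59.9). Fewer summits enter there by construction. Over all lists and alternatives, 359 results kept their call, 48 fell within the range on the same side of the random mean and 16 left the range. The other 16 lay below the random mean in place of above it; of these only histone genes were outside the range, and most had 0 genes with a summit, so no depletion is read from them. No replicate could be left out, and no paired analysis was possible because each group has 1 library. Start-site, exon, intron, repeat, promoter GC and sequence motif alternatives were not run. Depth limits weak peaks: 25% of summits hold 14 fragments or fewer.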

Other observations

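The 9 lists written after the strongest peaks were seen, and all tests of summits outside genes, were chosen after the result was known; of the explanations below, only the test on short genes was set before its result was seen. A further test set for the summits inside genes, of Arx binding near interneuron genes, was dropped after its value was seen, since it could not account for skin genes. That value met the limit set for it: with summits inside genes and lists matched on gene length, the interneuron percentile was 97.7. Epidermal genes held summits in 36 of 42 (85.7%, Wilson 72.2 to 93.3; random mean 17.8%), from basal keratins to the cornified envelope: Flg, which encodes filaggrin, held 18 summits and reached a fold of 29.3, Lce1a1 reached 34.1, Ivl 29.8 and Trp63, the master regulator of stratified epithelia, 20.5. Without the genes of the strongest peaks, 31 of 37 epidermal genes still held a summit. Hair follicle genes followed with 14 of 25, led by the inner root sheath keratins Krt71 (27.6) and Krt25 (25.4). Mature skeletal muscle genes held summits in 20 of 26 (76.9%) and dermal connective tissue genes in 21 of 26 (80.8%), while heart muscle had 1 of 12 and intestine, which includes the simple-epithelium keratins Krt8 and Krt18, 1 of 20, both within the random range (random means 17.8% and 19.1%). Housekeeping genes reached 28 of 30, with Actb at 37.3, and abundant transcripts of embryonic brain 18 of 40 (45.0%; random 24.6%). Outside protein-coding genes and pseudogenes the brain list had 6 of 40 genes near a summit (Cd24a, Ncam1, Sox4, Sox11, Tuba1a and Stmn4; adjusted share 0.0144 over the 9 lists). It did not pass adjustment in the other outside sets, with 6 of 40 and 0.131 outside protein-coding genes and 4 of 40 and 0.212 outside every gene. Of these lists 7 of the 26 dermal, 6 of the 26 mature muscle and 4 of the 40 brain genes also stand in another list; the telencephalon itself also uses the housekeeping genes.

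Among RNA genes that code for no protein, Malat1 held 5 summits with a highest fold of 31.9, Rn7s1 held 1 of 29.3, and H19, Rn7sk and Rmrp held 1 each, of 9.62, 7.34 and 5.97. Xist, Meg3, Neat1, Kcnq1ot1, Rpph1 and Snhg11 held 0. Summits per Mb of gene were highest in the shorter genes, at 68.0 in the second decile of length (median 2.85 kb), and fell to 3.38 in the longest (median 184.9 kb).

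Summits inside genes of skin, muscle and connective tissue are not what the telencephalic origin alone would lead one to look for. Active chromatin of telencephalic cells as the whole source was weighed by the brain list against the epidermal list. In the brain list, 37.5% had a summit inside (Wilson 24.2 to 53.0), against 85.7% of epidermal genes (72.2 to 93.3). Both lists were written after the strongest peaks were seen, and the epidermal one holds Krt5, Krt6b, Krt14, Krt15 and Krt16. Its high share was thus partly set by that choice, although most of its other genes also held a summit. Within this limit, the contrast argues against telencephalic chromatin as the whole source. A telencephalic share stays open, since the brain list was itself above the range (random mean 21.6%, adjusted share 0.0399). Other tissue of the same embryos as the whole source was weighed by developing against mature muscle. Of developing muscle genes, 25% had a summit inside (8.89 to 53.2), against 76.9% of mature ones (57.9 to 89.0), and the intervals did not overlap. The mature list was written after the strongest peaks were seen, however, and holds Acta1, Myh1 and Ttn. The developing list has 12 genes, some of which encode scarce regulators, and H19, an RNA abundant in embryos, held a summit. This contrast therefore does not decide against tissue of the same embryos. A candidate explanation is that many fragments derive from RNA (through cDNA) of another, skin- and muscle-rich sample. The test used 43 genes of 1 kb or less that held a summit and had no other annotated gene within 500 bp. There, 99.99% of peak bases lay inside the gene. The median was 80.9% (74.2 to 87.1) when the same peaks were placed at random within these genes. Neither end was crossed by 42 of the 43 peaks. Of these genes 29 encode histones, so this bears on the form of the signal and less on its tissue; how such material could have entered was not tested, and exon boundaries, which would test it directly, were not used here.

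Outside protein-coding genes and pseudogenes, summits near the cortical and interneuron lists may mark a smaller set with another origin, although summits there also lay near genes of other lists, such as Tle3 (6), Axin2, Rax, Msx1, Pecam1 and Rps24. Large flanks of developmental genes did not remove it (cortical percentile 99.7 with flank-matched lists), but the adjusted share of 0.119 leaves that open. The same source as inside genes is not excluded either. Of 124 epidermal, mature muscle, dermal and housekeeping genes, 0 were near such a summit, a percentile of 6.02, which random lists also give. Ribosomal protein genes, left out of that pool, had 2 of 40 (percentile 97.0, within the range). In the cortical and interneuron lists, the summits of Pou3f3, Foxg1, Mef2c, Pbx3 and Dlx1, and the Dlx6 summit in Dlx6os1, lay inside other annotated genes. RNA as a source stays open for them, while the others lay outside every gene. Arx occupancy is the biological explanation that the design names, and the interneuron list's percentile of 98.9 with an adjusted share of 0.280 does not decide for it (differences between lists were not tested). These explanations cannot be told apart without the sequence under the peaks, which was not used here.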
